A study of Mus musculus with 6 samples.

How the data were processed

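The data are bulk RNA sequencing of mouse liver sinusoidal endothelial cells from wild-type animals, in 6 libraries. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was selected on oligo(dT) beads, and libraries were made with an Illumina kit of New England Biolabs. Per the submitters' processing notes, the tools fastp 0.18.0, Bowtie2, HISAT2, StringTie 1.3.1 and RSEM were used, with no order or role given. The genome build, the annotation, the strand setting and the test of the authors are not given in the sources used here, so no genomic coordinates are printed. Of the 22298 Ensembl gene identifiers of the table, 22255 are also in GENCODE M21, and symbols were taken from the table.

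The deposited table holds, per the file headers, a count column and an FPKM column for each library, and all its per-library columns were used. The deposited counts are whole numbers that sum to 15999220 to 17871220 per library, and whether the authors rounded estimated counts is not stated. The FPKM values, fragments scaled by gene length and library size, were computed by the authors. The deposited group means are a score of the authors. They equal the plain mean within 0.001 for 14 of 11375 genes with a mean FPKM above 1 in the libraries labelled aging, and for 17 of 11430 in those labelled control. The log2 fold change, p-value and FDR columns are a comparison made by the authors, and they were used only where the authors' deposited table is named. Pathway terms came from the KEGG column of the same table, in which 7 entries are not reported here.

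Groups follow the titles and the group label. The age label gives 24 months for the libraries of the control group and 8 weeks for those titled aging, which goes against the titles, so group names stand for labels only. Within a group all pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 8.1 to 51.9). None was therefore taken as a repeat deposit of another. Libraries of the same mouse could also differ by more than sampling noise, which was not tested. The male gene Ddx3y had counts in all 6 libraries.

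The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13096 genes; 5264 genes had no count and 3938 fell below the filter. Libraries were scaled by TMM, with factors of 0.963 to 1.049. A robust quasi-likelihood model with group as its only term was fitted, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The standard error of a log2 fold change is the one the test implies, the absolute log2 fold change divided by the square root of F. CPM, counts scaled to a common library size, were computed here with the TMM factors, and means carry the SD over 3 libraries. Values near the detection limit rest on few counts, and the interval given for Gdf3 is an exact 95% binomial interval that covers counting error only.

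Gene lists were tested with fry of limma 3.58.1 on log2 CPM with a prior count of 2, adjusted over 25 lists. This test asks whether the genes of a list move one way on balance, not whether they differ from other genes. Beside it stand the number of members past the threshold over all genes and the number adjusted over the list alone. Camera, which asks whether the genes of a list differ from other genes, was run with an estimated correlation and with a preset one of 0.01. No list was called with the estimated correlation. The lists were LSEC identity, pan-endothelial, pericentral endothelium, periportal endothelium, capillary and basement membrane, Notch pathway, senescence and secretory phenotype, leukocyte adhesion and chemokines, interferon response, antigen presentation, cell cycle, oxidative phosphorylation, lysosome and autophagy, antioxidant response, and immediate-early and heat-shock genes. Further lists held markers of hepatocytes, macrophages, T and NK cells, B and plasma cells, neutrophils, stellate cells and fibroblasts, cholangiocytes and erythroid cells, and genes known as higher in old or in young mouse tissue. These lists, the tests, the named-gene rule and most alternatives were chosen before the data were examined. Lists of chaperones, cold-inducible, clock and glucocorticoid-responsive genes and the KEGG enrichment were added afterwards. The enrichment is a hypergeometric test on pathways of 10 to 300 genes, adjusted within each direction.

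Named genes were chosen by a fixed rule. Among genes past the threshold with a mean of at least 1 CPM, groups that did not overlap and a symbol that is no gene model, pseudogene or receptor segment, the 12 largest rises and 12 largest falls and the 6 smallest adjusted p-values per direction were taken. From each list up to 4 members were taken, the smallest adjusted p-values among those that passed or, where none passed, the smallest p-values. Other genes named from the lists or pathways were chosen after their values were seen; these include Msr1, Lyve1, Cdkn1a, Cdkn2a, Alb, Ttr, Hp, Ms4a1 and the pathway members. Reads of close copies such as Hspa1a and Hspa1b, the alpha globins, the Mrgpra2 genes and immunoglobulin genes can be shared, and without a stated strand setting overlapping genes cannot be told apart.

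The steps were tested on simulated data with the means, depths and trended dispersions of the libraries labelled aging and control and 200 genes changed. On 12992 simulated genes edgeR recovered 28.8% of 66 genes changed 1.5-fold, 78.8% of 66 changed 2-fold and 96.8% of 63 changed 4-fold, with 6 unchanged genes among 138 calls. With no change simulated, 1 gene and 0 of 25 lists were called. Genes were drawn independently, whereas the real lists had estimated correlations up to 0.94, so this does not give the error rate of the list tests. With 1678 genes called in the real data, the share recovered can also differ. The alternatives were size factors by relative log expression (RLE) and by upper quartile, the Wald test of DESeq2 1.42.0, no filter, a mean count of at least 10, limma with a trend on log2(FPKM + 1) for genes with FPKM of at least 1 in 3 libraries, a pseudocount of 0.1, no FPKM filter, leaving out each library, the replicate number as a block, and an absolute log2 fold change of at least 1. The mean log2 CPM of the 9 neutrophil markers as a covariate was added after the data had been seen.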

Results

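Liver sinusoidal endothelial cells, the fenestrated endothelium that lines the capillaries of the liver lobule, were profiled by poly(A)-selected RNA sequencing in wild-type mice. The series comprises 6 libraries in 2 groups of 3, named here by their titles: control replicates 1, 2 and 3, and aging replicates 2, 3 and 5. The study set cells of mice aged 24 months against cells of mice aged 8 weeks, but the label fields disagree. The libraries with the group control carry the age 24 months, and the libraries titled aging carry the age 8 weeks. The age of either group is therefore left unsettled, and each direction below is that of the libraries labelled aging relative to the libraries labelled control. Total counts per library ranged from 15999220 to 17871220, and 13096 genes had enough counts to be tested. Mitochondrial transcripts made up 2.74% to 3.33% of the counts. The labels do not say whether each library came from a separate mouse, so the p-values measure the spread between these libraries.

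The comparison of the groups asks which transcripts differ between sinusoidal endothelial cells of the mice at these ages. Among the genes with the smallest adjusted p-values were Ppp1r3a, Ccbe1, Dkk3, Hmga2, Dbp and Ddit4. Ppp1r3a (ENSMUSG00000042717), a glycogen-targeting subunit of protein phosphatase 1, rose 14.1-fold, from 3.45 ± 0.478 CPM to 49.0 ± 13.5 CPM (SD, n = 3 per group), a log2 fold change of 3.82 ± 0.25 (SE). Ccbe1 (ENSMUSG00000046318), a secreted factor needed for lymphatic vessel growth, rose 8.95-fold, and Dkk3 (ENSMUSG00000030772), a member of the Dickkopf family, rose 3.83-fold. Hmga2 (ENSMUSG00000056758), a chromatin protein of fetal and proliferating cells, fell from 6.02 ± 0.289 CPM to 0.272 ± 0.0904 CPM (SD, n = 3 per group), a log2 fold change of -4.43 ± 0.30 (SE). Dbp (ENSMUSG00000059824), a transcription factor driven by the circadian clock, fell 9.53-fold, with a log2 fold change of -3.25 ± 0.26 (SE), and Ddit4 (ENSMUSG00000020108), a stress-induced inhibitor of mTORC1, fell from 171 ± 9.38 CPM to 46.7 ± 8.11 CPM.

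The remaining genes with the smallest adjusted p-values were as well separated. Hdc, which makes histamine, rose from 173 ± 18.7 to 552 ± 54.1 CPM, and Chordc1, a co-chaperone of HSP90, rose 3.25-fold. Fam111a rose 2.94-fold. Arl4d, a small GTPase, had the smallest p-value of all tested genes and fell from 126 ± 9.48 to 37.9 ± 1.33 CPM (edgeR adjusted p = 0.000934). Atp9a and Dyrk2 fell, with log2 fold changes of -2.18 ± 0.15 and -1.64 ± 0.13 (SE). The edgeR adjusted p of these 12 genes lay between 0.000934 and 0.00192, and all 12 stayed past the threshold when any single library was left out.

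**Figure D1:**
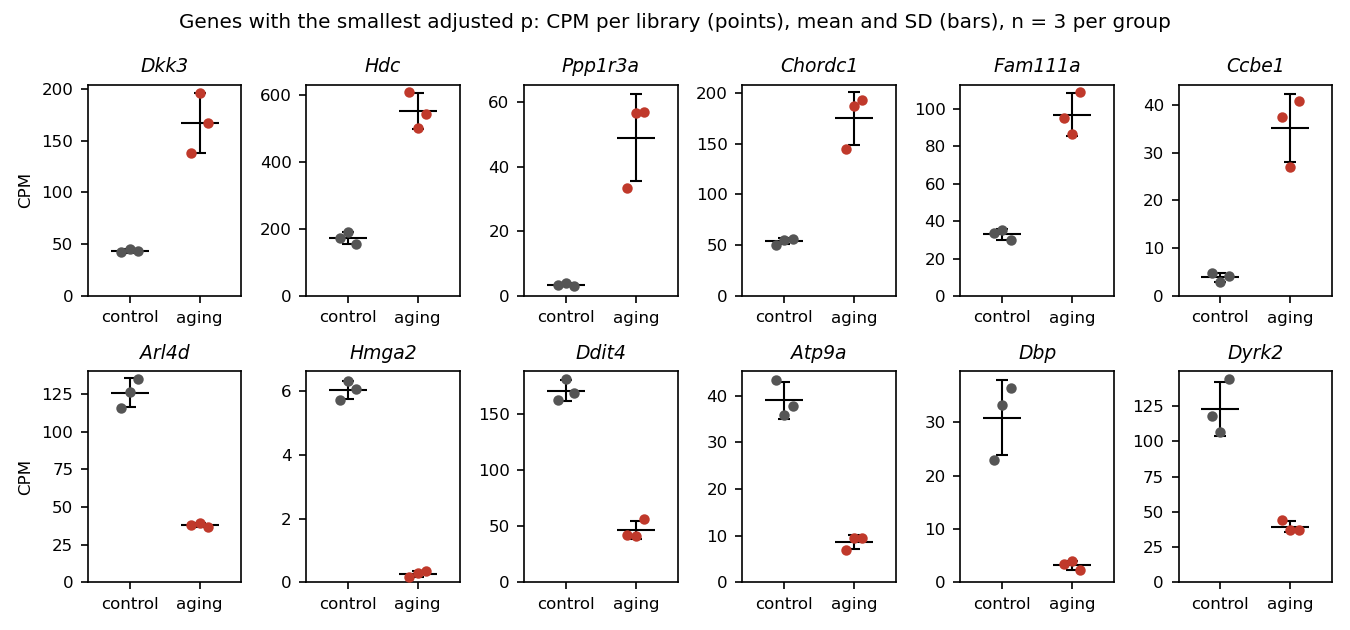
Expression in CPM (counts scaled to library size) in each library for the 6 higher and the 6 lower genes with the smallest adjusted p-values; points are libraries, the horizontal line is the group mean and the bars are the SD (n = 3 per group). In every panel the 3 libraries labelled aging lie apart from the 3 labelled control, as for Arl4d with 126 CPM against 37.9 CPM on average.

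Among the genes with the largest rises, several are known from neutrophils or other myeloid cells. The receptor genes Mrgpra2b and Mrgpra2a, the chemokine receptor Cxcr1 and the leukocyte receptor Tarm1 rose with log2 fold changes of 4.21 ± 0.52, 3.52 ± 0.44, 3.48 ± 0.62 and 3.79 ± 0.57 (SE). In the same libraries the summed neutrophil markers stood at 2381 ± 1395 CPM against 375 ± 142 CPM in the libraries labelled control (SD, n = 3 per group). The potassium channel Kcnj2 rose from 10.2 ± 2.07 to 113 ± 50.8 CPM. Rufy4, Ankrd22, Cpeb1 and Lypd6b rose with log2 fold changes between 3.52 and 3.87, from control levels under 0.5 CPM. Pcdhgc4 rose with a log2 fold change of 4.28 ± 0.77 (SE), where the authors' deposited table gives 0.92 with an FDR of 0.649. Gdf3 had 3 counts over the libraries labelled control and 115 over those labelled aging, a ratio of 36.6 with a 95% exact counting interval of 12.2 to 180. Pcdhgc4 shares exons with the other clustered protocadherins, and the Mrgpra2 genes are close copies, so their separate values are uncertain. Leaving out control replicate 1, 2 or 3 took Pcdhgc4, Rufy4, Tarm1 and Cxcr1 to edgeR adjusted p-values of 0.0516 to 0.0908. Ankrd22 was lost without control replicate 1 or 2 (edgeR adjusted p up to 0.0887) and Cpeb1 without control replicate 2 (edgeR adjusted p = 0.0539).

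The largest falls after Hmga2 included Stc1, a secreted glycoprotein hormone, from 12.8 ± 2.86 to 0.624 ± 0.510 CPM (SD, n = 3 per group). Lrch2, Cfap69 and Steap2 fell with log2 fold changes of -3.33 ± 0.45, -3.29 ± 0.36 and -2.84 ± 0.31 (SE). Gucy1b1, a subunit of the nitric oxide receptor guanylate cyclase, fell from 7.86 ± 0.374 to 1.17 ± 0.549 CPM. Gdf2, which encodes the endothelial ligand BMP9, and Siglech, a lectin of plasmacytoid dendritic cells, fell with log2 fold changes of -2.45 ± 0.45 and -2.36 ± 0.42 (SE). Fam107a and the liver enzymes Aox3 and Car3 fell by 2.56, 2.36 and 2.31 on the log2 scale. Siglech was lost without control replicate 1, 2 or 3, Gdf2 without control replicate 2 or 3, and Fam107a without control replicate 1, 2 or 3 or aging replicate 5 (edgeR adjusted p between 0.0516 and 0.113).

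**Figure D2:**
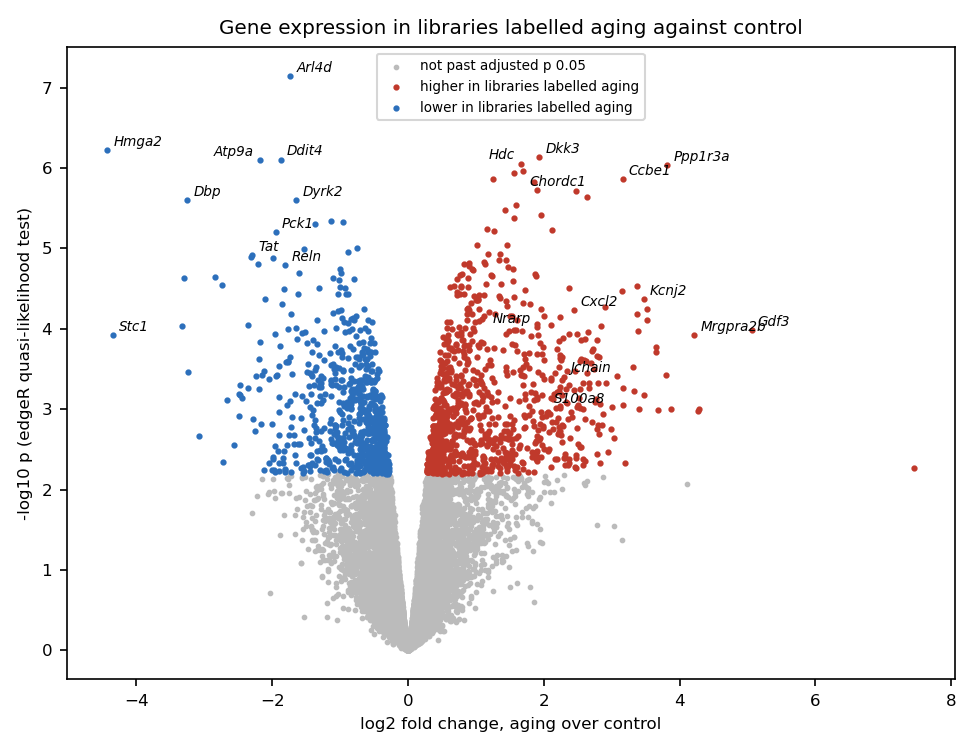
Log2 fold change of the libraries labelled aging over those labelled control against -log10 of the p-value from edgeR's quasi-likelihood test, 1 point per tested gene (13096 genes). Red and blue points are the 946 higher and 732 lower genes with an adjusted p under 0.05; grey points did not pass.

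Across the transcriptome, 1678 of the 13096 genes changed in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, with 946 higher and 732 lower in the libraries labelled aging. Of these, 437 rose and 228 fell at least 2-fold. The groups did not overlap for 4976 genes, 38% of those tested, where chance gives 10%. The first principal component of log2 CPM held 56.4% of the variance and separated the groups. With upper-quartile scaling the split of the calls was 823 higher and 969 lower, 45.9% higher against 56.4%. The count of changed genes fell to 664, 268 and 458 without control replicate 1, 2 and 3, and to 860 without aging replicate 3; with the mean log2 CPM of the neutrophil markers as a covariate, added after the data had been seen, it was 116. In that fit the median absolute log2 fold change of the 1678 genes went from 0.82 to 0.68 and their median SE from 0.15 to 0.24, and group accounts for 0.72 of the variance of the covariate, so lost calls do not show that neutrophils account for those genes.

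Of the 16 LSEC identity genes, which mark sinusoidal endothelium, none passed over all genes or adjusted over the list alone. Lyve1, a hyaluronan receptor, differed most, at 614 ± 57.2 against 258 ± 198 CPM, a log2 fold change of -1.25 ± 0.60 (SE); the groups did not overlap, but it did not pass (edgeR adjusted p = 0.207). Stab2, a hyaluronan scavenger receptor, had a log2 fold change of -0.31 ± 0.13 (SE), Oit3 -0.31 ± 0.11, Gpr182 0.33 ± 0.13 and Clec4g 0.28 ± 0.11, and none of them passed. None of the 13 pan-endothelial genes passed by either adjustment, and Kdr, the receptor VEGFR2, had a log2 fold change of -0.20 ± 0.09 (SE). The fry adjusted p was 0.69 for the LSEC identity list and 0.584 for the pan-endothelial list.

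Of 8 periportal endothelium genes 3 rose and 2 fell, and the same numbers passed when adjusted over the list alone. Efnb2, the arterial ephrin, rose from 106 ± 2.93 to 175 ± 14.5 CPM, the Notch ligand Dll4 rose with a log2 fold change of 0.90 ± 0.13 (SE), and Ntn4 rose with a log2 fold change of 0.55 ± 0.08 (SE). Adgrg6 and Msr1 fell, with log2 fold changes of -0.69 ± 0.15 and -0.40 ± 0.09 (SE). The list moved up by fry (adjusted p = 0.0439, median log2 fold change 0.37). Camera, which compares the list with other genes, did not call it (camera adjusted p = 0.766 with an estimated correlation). Of 8 pericentral endothelium genes none passed over all genes and 2 fell when adjusted over the list alone. Fabp4 and Wnt2 had log2 fold changes of -0.62 ± 0.18 and -0.43 ± 0.13 (SE; fry adjusted p = 0.296), and without aging replicate 3 this list was called downward (fry adjusted p = 0.0171). The periportal list missed the threshold without control replicate 1 or 2 or aging replicate 2 or 5 (fry adjusted p between 0.0789 and 0.134). Dll4 and Ntn4 missed it without control replicate 2, and Adgrg6 without control replicate 1, 2 or 3 (edgeR adjusted p between 0.0534 and 0.0963).

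In the Notch pathway 2 of 9 measured genes rose and 1 fell, and 2 rose and 2 fell when adjusted over the list alone. Nrarp, a feedback regulator induced by Notch, rose from 18.8 ± 6.42 to 69.8 ± 4.29 CPM, Dll4 rose as above, and the Notch target Hes1 fell from 105 ± 11.3 to 71.3 ± 4.88 CPM (fry adjusted p = 0.0851 for the list). Of 12 capillary and basement membrane genes only Cd34 fell, with a log2 fold change of -0.61 ± 0.10 (SE), and 3 fell when adjusted over the list alone (fry adjusted p = 0.0954, and 0.00761 without aging replicate 3). Hes1 was lost without control replicate 1 or 2, and Cd34 without control replicate 2 or 3 (edgeR adjusted p between 0.0516 and 0.0792).

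Of 14 measured senescence and secretory phenotype genes 4 rose and none fell, and 4 rose and 2 fell when adjusted over the list alone. Cxcl2, a chemokine that attracts neutrophils, rose from 112 ± 30.3 to 611 ± 160 CPM, and the cell cycle inhibitor Cdkn2b rose 3.71-fold. Il6 rose from 1.86 ± 0.438 to 3.96 ± 0.878 CPM and Gdf15 from 2.80 ± 0.741 to 5.37 ± 0.696 CPM. Cdkn2a and Cdkn1a, the inhibitors most used as senescence markers, had log2 fold changes of -0.24 ± 0.41 and -0.44 ± 0.47 (SE) and did not pass. The list's median log2 fold change was -0.02 and its mean 0.28, with fry upward (adjusted p = 0.0972). Neutrophil marker transcripts were higher in the same libraries, with a median log2 fold change of 2.47. Cdkn2b, Il6 and Gdf15 were lost without control replicate 1, 2 or 3 and without aging replicate 3, Il6 and Gdf15 also without aging replicate 2, and Cdkn2b and Il6 also without aging replicate 5 (edgeR adjusted p between 0.0562 and 0.148).

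Among leukocyte adhesion and chemokine genes, Cxcl10, an interferon-induced chemokine, fell from 95.6 ± 22.9 to 61.0 ± 5.98 CPM and was lost when any of the 6 libraries was left out (edgeR adjusted p between 0.0609 and 0.128). It was the only one of 9 measured members to pass, and none passed when adjusted over the list alone (fry adjusted p = 0.371). None of 16 interferon response genes passed by either adjustment. Their median log2 fold change was -0.03 and their mean 0.02, with fry downward (adjusted p = 0.998), and Stat2 had a log2 fold change of 0.32 ± 0.11 (SE). None of 14 antigen presentation genes passed by either adjustment, with H2-D1 at 0.31 ± 0.12 on the log2 scale (SE; fry adjusted p = 0.69). None of 22 cell cycle genes passed by either adjustment. Mki67 stood at 17.3 ± 2.99 against 29.0 ± 8.35 CPM and Pcna at 74.7 ± 1.81 against 93.4 ± 8.39 CPM (fry adjusted p = 0.283).

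None of the 12 lysosome and autophagy genes passed by itself by either adjustment, but they moved up together by fry (adjusted p = 0.0439, median log2 fold change 0.18). Camera, which compares the list with other genes, did not call it (camera adjusted p = 0.766 with an estimated correlation). The lysosomal proteases Ctsb and Ctsd had log2 fold changes of 0.31 ± 0.09 and 0.23 ± 0.09 (SE). The fry adjusted p of this list was 0.0224 without aging replicate 3 and between 0.0789 and 0.172 without any other single library. None of 18 oxidative phosphorylation genes passed by either adjustment, with a median log2 fold change of -0.10 and fry downward (adjusted p = 0.0851), and Uqcrc2 had a log2 fold change of -0.26 ± 0.07 (SE).

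Of 11 antioxidant response genes Hmox1, the heme oxygenase, rose from 108 ± 14.8 to 208 ± 18.1 CPM and catalase (Cat) fell from 151 ± 7.35 to 114 ± 11.6 CPM. Adjusted over the list alone, 2 rose and 1 fell. The median log2 fold change was -0.01 and the mean 0.08, with fry upward (adjusted p = 0.528). Of 14 immediate-early and heat-shock genes 2 rose and 2 fell, and 3 rose and 2 fell when adjusted over the list alone. Nr4a1 rose from 152 ± 28.7 to 393 ± 50.4 CPM and Atf3 from 74.7 ± 15.5 to 124 ± 12.2 CPM, while Jun fell from 1107 ± 169 to 505 ± 105 CPM and Egr1 from 929 ± 190 to 525 ± 39.2 CPM. The median was -0.07 and the mean -0.05 on the log2 scale, with fry upward (adjusted p = 0.998). Cat was lost without control replicate 1, 2 or 3 or aging replicate 3, Egr1 without control replicate 2 or aging replicate 3, and Atf3 without control replicate 2 or 3 or aging replicate 3 (edgeR adjusted p between 0.0529 and 0.135).

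Transcripts of other cell types differed between the groups. All 9 neutrophil markers were higher in the libraries labelled aging; 5 rose over all genes and 9 when adjusted over the list alone. The calprotectin subunits S100a8 and S100a9 rose from 56.7 ± 23.0 to 455 ± 289 CPM and from 129 ± 49.5 to 922 ± 548 CPM, and Retnlg and the receptor Csf3r rose 6.82-fold and 5.32-fold. The list's fry adjusted p was 0.0954. In camera its adjusted p was 0.000429 with the preset correlation of 0.01, the only list called there, and that call was lost with an adjusted p = 0.766 with an estimated correlation. The summed neutrophil CPM was 3985 in aging replicate 2, 1704 in aging replicate 3 and 1454 in aging replicate 5, against 457, 455 and 211 in control replicates 1, 2 and 3. S100a8, S100a9 and Csf3r were lost without control replicate 1, 2 or 3, and Retnlg without control replicate 1 or 2 (edgeR adjusted p between 0.0522 and 0.0781).

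Of 10 B and plasma cell markers 3 rose over all genes and 4 when adjusted over the list alone. The antibody-joining chain Jchain rose from 3.82 ± 1.24 to 32.4 ± 15.3 CPM, Igkc from 14.5 ± 6.19 to 101 ± 68.1 CPM and Igha from 3.43 ± 1.33 to 12.4 ± 3.57 CPM, whereas the B cell gene Ms4a1 had a log2 fold change of 0.21 ± 0.64 and did not pass (SE; fry adjusted p = 0.518 for the list). Of 11 measured T and NK cell markers Cd8a rose, from 1.25 ± 0.646 to 5.72 ± 3.29 CPM, and 1 rose and 2 fell when adjusted over the list alone. That list's median log2 fold change was -0.29 and its mean 0.18, with fry downward (adjusted p = 0.979). None of 12 macrophage markers passed by either adjustment. Clec4f, specific to Kupffer cells, stood at 414 ± 95.3 against 308 ± 149 CPM, and Timd4 at 41.2 ± 7.91 against 16.8 ± 7.41 CPM (fry adjusted p = 0.69). Jchain and Igha were lost without control replicate 2 or 3, Igkc without control replicate 1, 2 or 3 or aging replicate 2 or 3, and Cd8a without control replicate 1, 2 or 3 or aging replicate 3 (edgeR adjusted p between 0.0521 and 0.135).

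Of 14 hepatocyte markers 3 fell over all genes, and 2 rose and 3 fell when adjusted over the list alone. The gluconeogenic enzyme Pck1 fell from 33.1 ± 4.85 to 8.57 ± 1.76 CPM, the tyrosine aminotransferase Tat from 23.7 ± 2.57 to 4.82 ± 1.63 CPM and Fabp1 from 20.5 ± 2.70 to 9.82 ± 1.87 CPM. Albumin (Alb), the most abundant of them, stood at 509 against 520 CPM, a log2 fold change of 0.03 ± 0.11 (SE); the median of the list was -0.29, with fry downward (adjusted p = 0.106). Of 12 stellate cell and fibroblast markers 3 fell, which were Reln, Dcn and Lrat, and 1 rose, and the same numbers passed when adjusted over the list alone. Reln fell from 13.7 ± 2.12 to 3.92 ± 0.654 CPM (fry adjusted p = 0.0972). None of 6 cholangiocyte markers and none of 5 measured erythroid markers passed by either adjustment, with Spp1 at -0.67 ± 0.20 and Alas2 at -0.82 ± 0.33 on the log2 scale (SE; fry adjusted p = 0.518 and 0.528). Fabp1 was lost without control replicate 2, Dcn without control replicate 1 or 2, and Lrat without any single library except aging replicate 5 (edgeR adjusted p between 0.0534 and 0.0987).

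**Figure D3:**
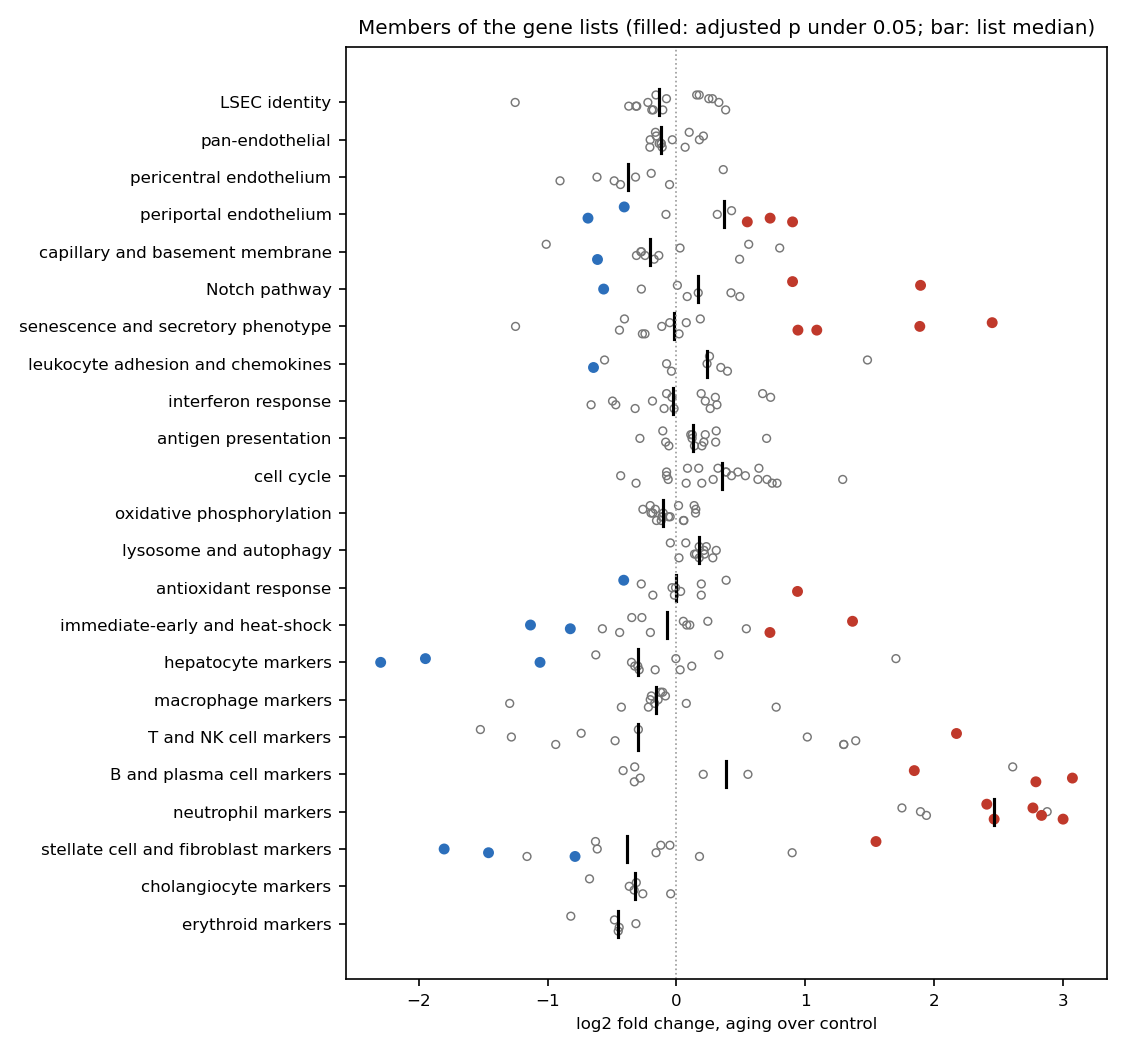
Log2 fold change, libraries labelled aging over control, of each measured member of the 23 lists of pathways and cell types; filled points had an adjusted p under 0.05 over all genes and the black bar is the list median. The neutrophil markers have the highest median, 2.47, while the LSEC identity and pan-endothelial lists have no filled point.

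A list of genes known as higher in old mouse tissue, fixed from background knowledge, had 4 of 9 measured members higher in the libraries labelled aging and none lower. These were Jchain, Igha, Igkc and Gpnmb, and 6 rose when adjusted over the list alone (fry adjusted p = 0.182). A list of genes known as higher in young tissue had 2 of 10 measured members lower and none higher, the same when adjusted over the list alone (fry adjusted p = 0.0954, 0.0415 without control replicate 2 and 0.118 to 0.412 without any other single library). These were the imprinted genes Peg3, from 9.33 ± 2.23 to 2.58 ± 0.273 CPM, and Plagl1, from 55.9 ± 6.05 to 20.0 ± 5.96 CPM. Of the first list, 4 measured members are also B and plasma cell markers. Gpnmb was lost without any single library except aging replicate 5, and Plagl1 without control replicate 2 (edgeR adjusted p between 0.0526 and 0.129).

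Pathway enrichment by the KEGG terms of the deposited table was added after the data had been seen. Over 326 pathways and a background of 5775 tested genes with a pathway, the NF-kappa B signaling pathway held 23 higher genes of 105 where 8.1 were expected (hypergeometric adjusted p = 0.000572), among them Cxcl2, Il1b, Tlr4, Myd88 and Ptgs2. Cytokine-cytokine receptor interaction held 30 of 166 (adjusted p = 0.00088) and the Toll-like receptor pathway 16 of 77 (adjusted p = 0.00853). Cytokine-cytokine receptor interaction holds the neutrophil receptor genes Csf3r, Cxcr1 and Cxcr2, and neutrophil markers were higher in the same libraries. The higher genes of the NF-kappa B pathway include the antibody genes Igha, Ighg2b and Ighg2c. Among lower genes, tryptophan metabolism held 11 of 37 where 2.0 were expected (adjusted p = 0.000687), including Tdo2, Kmo and Aox3. Tyrosine metabolism held 8 of 22 (adjusted p = 0.00165), including Tat, Hpd, Hgd and Fah, and arginine biosynthesis held 6 of 17 (adjusted p = 0.0136), including Cps1, Otc and Ass1. Many of these lower enzymes are best known from hepatocytes. In the same libraries the hepatocyte markers Pck1, Tat and Fabp1 fell. Alb, Ttr and Hp had log2 fold changes of 0.03 ± 0.11, 0.00 ± 0.10 and 1.71 ± 0.46 (SE) and did not pass over all genes. Hp stood at 235, 106 and 86.6 CPM in aging replicates 2, 3 and 5, the same order as the summed neutrophil markers. Its value is therefore not read as hepatocyte content. Genes of a pathway are not independent, so these p-values describe overlap and not replicate error.

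The authors' deposited table lists 3186 genes with an FDR under 0.05, of which 1815 are higher and 1371 lower. In the authors' deposited table and in the edgeR test 1377 genes were called in both, and 1372 of them had the same direction. A further 301 were called in the edgeR test only, and 1696 of the tested genes in the authors' deposited table only. Over the tested genes, which are not independent replicates, the correlation of the log2 fold changes with those in the authors' deposited table was 0.86. Of the named genes that passed in the edgeR test, Pcdhgc4, Ntn4, Hes1, Gdf15, Cxcl10, Hmox1, Cat, Egr1 and Lrat have an FDR above 0.05 in the authors' deposited table. Some named genes that did not pass in the edgeR test have an FDR under 0.05 there. Examples are Mki67 (FDR 0.00553), Fabp4 (0.00308) and Uqcrc1 (0.000684). Cxcl10, which fell by edgeR, has a log2 fold change of 0.57 with an FDR of 0.616 in the authors' deposited table. The test behind the authors' values is not given in the sources used here.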

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

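The neutrophil covariate was chosen after the data had been seen; the other settings were planned. The 1678 changed genes (946 higher, 732 lower) became 1682 with RLE factors, 1792 with upper-quartile scaling, 2348 with DESeq2, 1495 with no filter, 1658 with a mean count of at least 10, 1365 with limma on log2(FPKM + 1) and 1379 with a pseudocount of 0.1. The majority turned to lower genes with upper-quartile scaling (823 higher, 969 lower) and with limma on FPKM (640 higher and 725 lower, and 654 and 725 with a pseudocount of 0.1). Larger moves came with limma on FPKM with no filter, 981 genes (470 higher, 511 lower), with 17049 genes tested against 13096. Requiring an absolute log2 fold change of at least 1 left 665 genes, 437 higher and 228 lower, by its construction. DESeq2 called 1356 higher and 992 lower. Leaving out 1 library gave 268 to 2121 changed genes, 146 to 1253 higher and 122 to 868 lower; the fits hold fewer libraries, but the cause was not tested. The covariate left 116 genes (89 higher, 27 lower), 94 of them among the 1678; the median absolute log2 fold change of the 1678 genes went from 0.82 to 0.68 and the median SE from 0.15 to 0.24, where group accounts for 0.72 of the variance of the covariate. Of the genes called, none changed sign under RLE, upper-quartile, DESeq2, the count filters, any left-out library or the replicate block, 6 to 7 did so in the limma settings and 3 with the covariate.

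The number of lists called by fry, 2, was 1 with RLE factors and 0 with no filter, limma on FPKM or the replicate block. It was 0 to 4 when 1 library was left out, and the cause was not tested. Camera called 0 lists with an estimated correlation and 1 with the preset correlation, but it asks another question than fry. The replicate block, with numbers 2 and 3 in both groups, gave 1698 genes (1048 higher, 650 lower). The deviations of libraries with the same number correlated at -0.06 and -0.04, so the numbers were not taken as pairs.

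Of 113 named genes, 69 passed. Of these 69, all kept their call with RLE factors and DESeq2, 68 with upper-quartile scaling, 67 with no filter, 56 of 59 tested with limma on FPKM, 62 with the block and 18 with the covariate; 34 kept it under each left-out library, and none changed direction. Some results not past the threshold changed direction. With the covariate the log2 fold change of Oasl2 was -0.60, of Ciita -0.64, of Nlrc5 -0.08, of Map1lc3b -0.04 and of Lyz2 -0.20. With the replicate block that of C1qa was 0.17, of Hba-a1 0.22, of Hba-a2 0.29 and of Hbb-bt 0.40; with a library left out it ranged from -0.52 to 0.03 for C1qa and from -0.51 to 0.03 for Krt19. List directions turned, as adjusted p-values of fry or camera, for interferon response (0.399 with the block, 0.115 to 0.998 with a library left out), immediate-early and heat-shock (0.821 with limma on FPKM, 0.981 and 0.915 in camera with the estimated and preset correlation, 0.721 to 0.966 with a library left out, turned at 0.796 and 0.876), macrophage markers (0.808 with the block, 0.358 to 0.906 with a library left out, turned at 0.881), T and NK cell markers (0.977 with no filter, 0.437 with the block, 0.503 to 0.991 with a library left out) and erythroid markers (0.399 with the block). The cause was not tested. At 15999220 counts or more per library, genes under about 1 CPM rest on few counts, and most 1.5-fold changes were missed in simulation.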

Other observations

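Chosen only after the results had been seen were the tests of the chaperone, cold-inducible, clock and glucocorticoid lists, the heat-shock bound, the correlation of the neutrophil markers, the medians of other cell types, the use of the old-tissue and young-tissue lists for the age labels, and the neutrophil covariate. The fry tests of those 2 tissue lists and the splits were planned, and the bound on the count of clock genes was set before these genes were examined. Of 22 chaperones and co-chaperones of the HSP90 and HSF1 system, 17 rose in the libraries labelled aging and none fell, with a median log2 fold change of 1.20 (fry p = 0.00159; camera p = 0.0674 with an estimated correlation). Hsph1 rose from 29.4 to 262 CPM, Dnaja1 from 182 to 683 CPM, Hspa8 from 1017 to 2830 CPM and Hsp90aa1 from 174 to 515 CPM. The strongly heat-inducible Hspa1a and Hspa1b had log2 fold changes of -0.35 ± 0.39 and -0.20 ± 0.39 (SE) and did not pass. Hspa1a stood at 249, 202 and 575 CPM in control replicates 1, 2 and 3, and at 255, 316 and 237 CPM in aging replicates 2, 3 and 5. Hspa1b stood at 292, 218 and 635 CPM and at 291, 393 and 312 CPM in the same libraries. Both negative signs therefore lean on control replicate 3. The cold-inducible RNA-binding genes Cirbp and Rbm3 both fell, with log2 fold changes of -1.72 ± 0.21 and -0.60 ± 0.10 (SE; fry p = 0.00199; camera p = 0.0856 with an estimated correlation). Of 8 glucocorticoid-responsive genes 3 fell, Klf9 from 566 to 227 CPM, Tsc22d3 from 224 to 156 CPM and Ddit4 as in the results (fry p = 0.00307; camera p = 0.0942 with an estimated correlation). With the neutrophil covariate 16 of the 22 chaperones passed, with a median absolute log2 fold change of 1.62.

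The chaperone rise together with the fall of Dbp may reflect collection of the 2 groups at different phases of the daily cycle, since clock output, body temperature and glucocorticoids follow the time of day. Of 12 other clock genes 4 passed, the bound set before they were examined: Nfil3 rose, and Per2, Nr1d2 and Tef fell, where 1.5 were expected by chance (exact hypergeometric p = 0.057). As a list they had a fry p = 0.128 and a camera p = 0.501 with an estimated correlation. Both tests ask for movement in 1 direction, and these genes moved both ways, so the 2 p-values cannot decide on a phase. The bound was met only with Nfil3, at 15.7, 13.4 and 10.2 CPM in control replicates 1, 2 and 3 and at 101, 46.7 and 39.0 CPM in aging replicates 2, 3 and 5, the same order as the summed neutrophil markers. Without Nfil3, set aside only after its values were seen, the count is 3, under the bound. Arntl, Npas2 and Cry1 were higher and Nr1d1 and Hlf lower with groups that did not overlap, but did not pass. Of the 12, groups overlapped only for Clock, Per1 and Per3. They did not overlap for any of the other clock genes, where 38% of all tested genes had groups that did not overlap. A different phase therefore stays open and is not shown. A stronger heat-shock response during cell isolation stays open: the higher of the Hspa1a and Hspa1b log2 fold changes plus 2 SE was 0.57, so a rise of 0.5 is not excluded, and immediate-early genes moved both ways. Times of collection are not in the labels used here, and age, the difference the design names, also stays open and untested for this pattern.

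The higher neutrophil transcripts may come from neutrophils among the collected cells. The 9 markers moved together between libraries of a group, with an estimated correlation of 0.88. The macrophage markers, which also mark a cell type, had an estimated correlation of 0.94. The interferon response, which is no list of cell type markers, had 0.76, so the correlation alone cannot decide the source. The most abundant markers were at 922 CPM for S100a9 and 708 CPM for Csf3r on average in the libraries labelled aging. A lower share of endothelial cells that raised every other cell type alike is argued against. The highest median among the macrophage, hepatocyte, stellate, cholangiocyte and erythroid lists was a log2 fold change of -0.15. B and plasma cell markers were not among these lists. An endothelial share lowered by neutrophils alone would not raise those lists, so it stays open. Median log2 fold changes were -0.13 for LSEC identity and -0.12 for pan-endothelial genes. B and plasma cell markers were higher on average (4.79-fold in sum, median log2 fold change 0.38), but not in every library. Their summed CPM was 509, 782 and 142 in aging replicates 2, 3 and 5. In control replicates 1, 2 and 3 it was 148, 87.8 and 63.0, so aging replicate 5 lay below control replicate 1. A change in those cells stays open as well. Whether the purification admitted more neutrophils or the livers held more cannot be read from these data, and a difference with age stays open.

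The age label and the group label of each library disagree, and one candidate explanation is that the age values of the groups were exchanged. The fry directions of the lists fixed as higher in old and in young tissue were up and down in the libraries labelled aging, as that exchange would give, but neither list passed with all libraries; the larger adjusted p was 0.182. The young-tissue list passed only without control replicate 2 (fry adjusted p = 0.0415, against 0.118 to 0.412 without any other single library), its median log2 fold change was -0.11, and its members Mki67 and Top2a went the other way, at 0.74 ± 0.24 and 0.70 ± 0.30 (SE). Of the 4 genes of the old-tissue list that passed, 3 are antibody genes, whose level also depends on plasma cells among the collected cells, so the exchange and a wrong group name cannot be told apart here.

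Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real one, which is the real split itself with 1678 genes. The highest of the other splits gave 0 genes by edgeR, with 158 to 977 genes at an unadjusted p under 0.05 against 4098. Every other split puts libraries of both labels in each of its groups. A difference between the labels then adds to the spread within those groups and lowers the number of calls. These splits therefore cannot show how many genes would be called by chance. With 10 splits the share is never under 0.1, too few to reach 0.05.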
